A study of Mus musculus with 8 samples.

How the data were processed

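RNA was measured in 8 cultures of mouse P19 cells, an embryonal carcinoma line that can be turned into neurons or muscle in culture, each carrying a different lentivirus or a different virus dose. Each culture gave 1 poly(A)-selected library, sequenced on an Illumina HiSeq instrument, per the labels. The deposited table holds raw counts of reads per Ensembl gene and library, with whole numbers throughout. Per the submitters' processing notes, the authors used CASAVA 1.8.2, TopHat2 2.0.8 and the mm9 genome build. The counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical paralogs, such as the clustered myosin heavy chains and the muscle actins, can be split between genes in a way that cannot be checked. The table has 37558 genes, of which 12544 had no count in any library, and its 8 library columns were all used. Gene symbols came from a newer annotation (GENCODE on another build than mm9), matched by Ensembl identifier for 32850 genes, or 87.5%. Genes with no symbol held 1.24% to 1.53% of the counts and stayed in the library totals. No coordinates were taken from that annotation.

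Library totals ran from 26410500 counts for the chimera to 43984066 for GFP. At these totals 3 counts, the floor used for a gene with a count of 0, correspond to 0.073 to 0.115 CPM. CPM here are counts scaled to a common library total after TMM scaling over the 8 libraries in edgeR 4.0.16, with TMM factors from 0.9348 to 1.085. The upstream steps limit what the values can show in 3 ways. Poly(A) selection leaves out transcripts without a tail, counts per gene do not separate a delivered coding sequence from the cell's own gene, and counts per gene do not separate isoforms.

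Every group had 1 library. For comparisons of single libraries no test of groups was made. A chi-square test per gene on the counts of 2 libraries was used only to count genes that differed by more than counting noise, and it compares libraries, not groups. A gene met the size rule when it was at least 4-fold apart on log2(CPM + 0.5) with at least 5 CPM in the higher library. Ratios named in the text are ratios of CPM with exact conditional binomial (Clopper-Pearson) 95% intervals on the 2 counts. Such intervals cover counting error only, since reads from PCR are not independent molecules and no second culture was measured. A fold against a count of 0 was computed against the floor of 3 counts per library, and the lower bound of its interval is given as an at-least value. The 13 gene lists, fixed before the data were examined, were skeletal muscle structure, myogenic regulators, neuronal structure, neurogenic regulators, pluripotency, neural progenitor and Notch, cell cycle, cardiac and smooth muscle, fibroblast and matrix, endoderm and mesoderm, glia and neural crest, E-proteins with Id, Pbx and Meis, and interferon and stress. A list member was measured at 1 CPM or more in at least 1 library. Each list's median log2 ratio was set against 10000 random lists matched on mean expression in 20 bins, as a description of these libraries.

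MyoD-activated genes were those meeting the size rule in MyoD over both GFP and NeuroD2, NeuroD2-activated genes the reverse, and shared genes met it in both over GFP while lying under 2-fold apart. The 4 libraries of the chimera and the WCS mutant, each with and without the MOI 100 label, were fitted with edgeR's quasi-likelihood test on construct and MOI label, after filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. That fit has 1 residual degree of freedom, and no standard errors are given for its fold changes. Its p-values measure how alike the construct difference was at both MOI labels, not the spread between separate cultures of a group. Lists were tested in the same 4 libraries with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation beside it, and with fry. Comparisons sharing the GFP library were set beside 20 simulations of unchanged libraries against the same GFP library.

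Named genes followed a rule fixed before the data were examined: Myod1 and Neurod2 in all libraries, a fixed panel of 30 markers, in each comparison the 6 highest and the 6 lowest genes by the interval bound nearest to no change, in each list the 4 members with the largest ratio, and in the 4-library test the 10 genes with the smallest adjusted p in each direction. Predicted or unnamed gene models were skipped. Genes named outside the rule are marked as chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors, total gene counts, no minimum level, a pseudocount of 2 CPM, an 8-fold threshold, other set definitions, the DESeq2 Wald test, other filters, fits without the block, a fit on all 8 libraries and fits without each of the 4 libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data. In simulated counts for the WCS against chimera fit over 16079 genes, 69 of 100 genes changed 2-fold and 98 of 100 changed 4-fold were recovered, with 0 unchanged genes called. These counts were drawn with the dispersion of that same fit and with no MOI effect. They check the steps and give no error rate for the calls in the real libraries. In simulated counts for MyoD over GFP over 37558 genes, 100 of 100 genes changed 8-fold and 7 of 100 changed 3-fold met the size rule, with 0 unchanged genes meeting it.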

Results

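The study asked whether the DNA-binding domain of a lineage-driving transcription factor sets the lineage it drives. MyoD (gene Myod1, ENSMUSG00000009471) drives skeletal muscle and NeuroD2 (gene Neurod2, ENSMUSG00000038255) drives neurons. Both are basic helix-loop-helix (bHLH) proteins. P19 cells were transduced with lentivirus carrying GFP, MyoD, NeuroD2, a chimera of MyoD with its bHLH domain replaced by that of NeuroD2, or mutants of that chimera labelled WC and WCS, which the labels do not define further. The chimera and WCS were also delivered at a multiplicity of infection (MOI) of 100. The MOI of the other 6 libraries is not given in the labels. All cultures were moved to a neuronal medium after infection. Each of the 8 groups had 1 library and so no replicate. Total counts were 43984066 for GFP, 27754554 for MyoD, 26410500 for the chimera, 28113664 for the chimera at MOI 100, 31381610 for WC, 29720496 for WCS, 29407015 for WCS at MOI 100 and 27604056 for NeuroD2. In all, 15547 genes reached 1 CPM in at least 1 library.

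The delivered factors followed the labels. Myod1 stood at 0.68 CPM in GFP and 0.80 in NeuroD2, against 296 CPM in MyoD, 116 in the chimera, 106 in WC and 77.3 in WCS. At MOI 100 it reached 555 CPM in the chimera and 857 CPM in WCS. Neurod2, whose bHLH segment is part of the chimera, stood at 2.5 CPM in GFP and 180 CPM in NeuroD2. It had 0 counts in MyoD and 13.8, 15.8 and 14.6 CPM in the chimera, WC and WCS. At MOI 100 it stood at 73.3 CPM in the chimera and 130 CPM in WCS. Counts per gene do not separate delivered from endogenous transcripts.

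**Figure D1:**
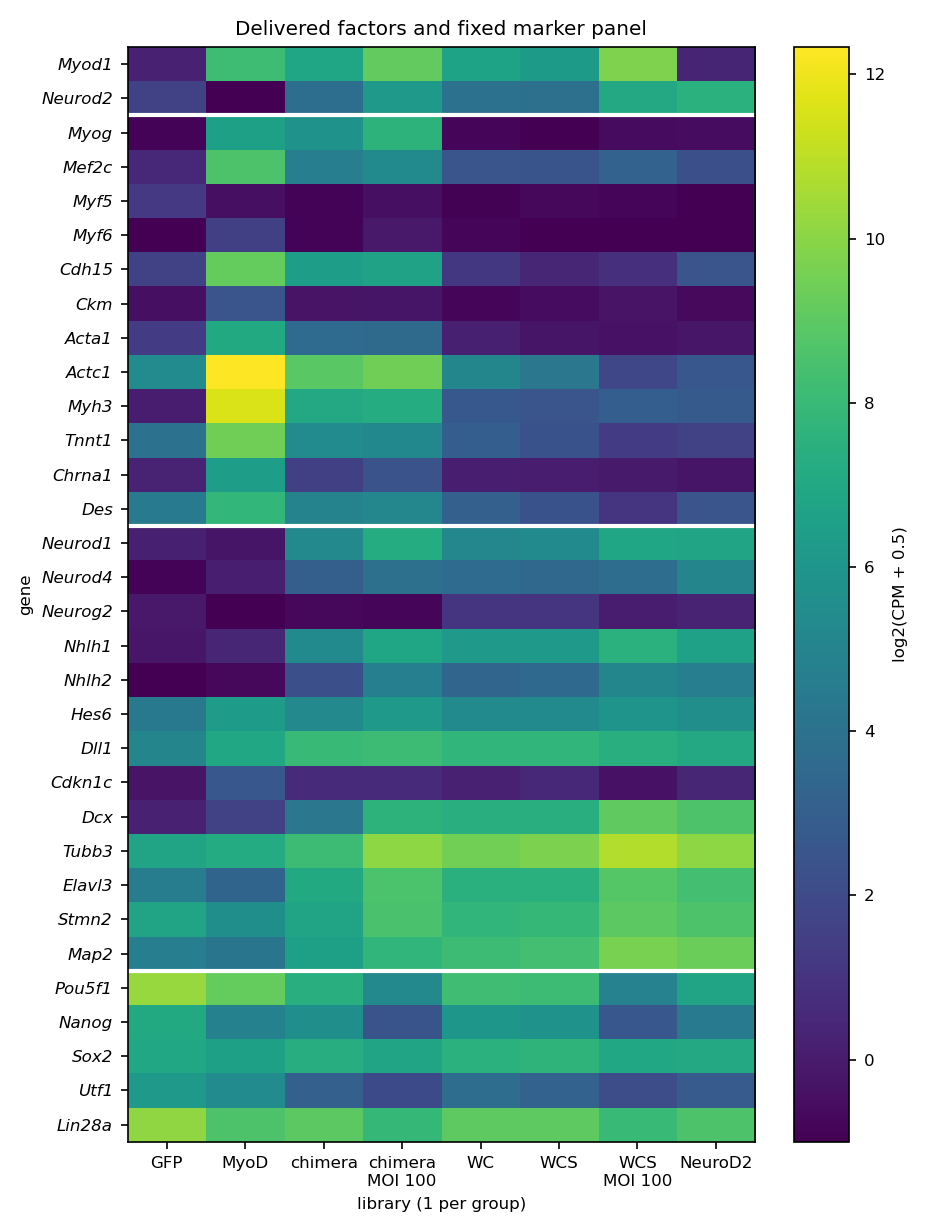
Levels of Myod1, Neurod2 and the 30 fixed marker genes (rows) in the 8 libraries (columns), as log2(CPM + 0.5) by colour, with white lines between delivered factors, muscle genes, neuronal genes and pluripotency genes. Myog stands at 95.1 CPM in MyoD, 58.2 in the chimera and 197 in the chimera at MOI 100, and under 0.2 CPM in the other 5 libraries.

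The first comparison asked what MyoD turns on in these cells. Skeletal muscle genes were far higher in MyoD than in GFP. Of 68 measured skeletal muscle structure genes, 61 were at least 4-fold higher and 0 at least 4-fold lower, with a median log2 ratio of 6.12 (95% order-statistic interval over members 5.01 to 6.51), and 0 of 10000 matched random lists reached that median. Myh3, the embryonic myosin heavy chain, stood at 3060 CPM against 0.51 CPM. Tnni1, a slow-muscle troponin, was 3854-fold higher (interval 1505 to 14149), Tnnt2, a cardiac and embryonic muscle troponin, 2295-fold (1164 to 5317), and Actc1, a sarcomeric actin, 122-fold (116 to 128). Among 28 myogenic regulators 16 were at least 4-fold higher. They included Myog, the myogenic bHLH factor myogenin, at 95.1 against 0.0486 CPM, Mef2c, a muscle transcription factor, 413-fold higher (302 to 581), Cdh15, muscle cadherin, 221-fold (183 to 270), and Mymk, a myoblast fusion protein, 2880-fold (797 to 23788). Myf5 went the other way, at 0.23 against 1.78 CPM. This was not particular to MyoD, since Myf5 stood at 0.243 CPM or less in every library other than GFP.

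Neuronal structure genes did not follow in MyoD. Of 81 members 4 were at least 4-fold higher and 6 at least 4-fold lower, with a median of -0.42. Reln, a secreted guidance protein, was 19.0-fold higher (15.2 to 24.1) while Gng3, a neuronal G protein subunit, was 12.9-fold lower (11 to 15.3). The 56 neurogenic regulators had a median of 0.12. Pluripotency genes had a median of -0.08, inside the random range of -0.28 to 0.22, although Nanog was 4.69-fold lower (4.34 to 5.06) and Fgf5, a growth factor of primed cells, was 57.7-fold higher (39.7 to 87.3). The other pluripotency genes of the fixed panel were lower as well: Lin28a 2.8-fold, Pou5f1 2.09-fold, Utf1 1.64-fold and Sox2 1.3-fold. The cardiac and smooth muscle list was split: Myh6, a cardiac myosin, was 139-fold higher (97.4 to 207), and Tagln, a smooth muscle actin-binding protein, was 18.2-fold lower (15.5 to 21.5). Rsad2, an interferon-induced gene, was 203-fold higher (86.7 to 628) at 24.7 CPM. The next largest ratios of the interferon and stress list were Egr1 (15.3-fold higher), Jun (3.83-fold lower) and Trib3 (3.55-fold higher). Bst2 of the same list stood at 12.4 CPM in MyoD against 17.2 CPM in GFP, so Rsad2 does not stand for the list. The size rule was met by 428 genes higher and 143 lower.

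NeuroD2 against GFP gave the neuronal counterpart. Of 81 neuronal structure genes 49 were at least 4-fold higher and 0 lower, with a median of 2.38 (2.02 to 2.98), and 31 of 56 neurogenic regulators were at least 4-fold higher, with a median of 2.56. Dcx, doublecortin of migrating neurons, stood at 397 against 0.68 CPM, 583-fold higher (403 to 877). Chgb, a secretory granule protein, was 341-fold higher (245 to 489), Slc17a6, a vesicular glutamate transporter, 499-fold (213 to 1538), and the bHLH genes Neurod1 and Nhlh1 183-fold (124 to 283) and 255-fold (157 to 446). Nhlh2 was at least 279-fold higher (344-fold against the floor). Pluripotency genes were lower, with a median of -1.43. Pou5f1, which encodes Oct4, was 11.2-fold lower (10.8 to 11.6) and Utf1 10.8-fold lower (9.29 to 12.6). Skeletal muscle structure genes had a median of -0.07, with 1 member at least 4-fold higher and 6 lower. In the neural progenitor and Notch list 14 of 38 were at least 4-fold higher, including Olig2, a spinal progenitor factor, 223-fold (117 to 490) and the Notch target Hes5 126-fold (76.4 to 227). The size rule was met by 680 genes higher and 249 lower.

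Set directly against each other, MyoD and NeuroD2 differed by the size rule at 410 genes higher in MyoD and 686 higher in NeuroD2. Actc1 was 907-fold higher in MyoD (778 to 1064). Klhl41, a sarcomere-associated protein, was 1990-fold higher (1082 to 4150). Kcnd3, a potassium channel, was 577-fold higher in NeuroD2 (280 to 1436) and Myt1, a neurogenic zinc-finger factor, at least 232-fold (286-fold against the floor). Scaling to total gene counts in place of TMM shifts the median of all measured genes by -0.14 on the log2 scale in this comparison, by 0.14 in NeuroD2 over GFP, by 0.12 and 0.20 in the chimera and WCS at MOI 100 over GFP, and by 0.12 in WCS at MOI 100 over WCS. Ratios here are relative to the TMM scale.

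The chimera was compared with GFP to ask which of these programs it turns on. Genes of both were higher. Of 68 skeletal muscle structure genes 25 were at least 4-fold higher and 0 lower, with a median of 2.13 (1.49 to 2.36). Of 81 neuronal structure genes 18 were at least 4-fold higher and 1 lower, with a median of 1.02 (0.48 to 1.42). Among muscle genes Myog was 1197-fold higher (331 to 9890), Myh3 259-fold (169 to 418), Ttn, the giant sarcomere protein titin, 132-fold (104 to 172), Musk, a kinase of the neuromuscular synapse, 121-fold (80.0 to 194) and Cdh15 33.7-fold (27.8 to 41.2). Among neuronal genes Neurod1 was 63.5-fold higher (42.7 to 98.5), Nhlh1 101-fold (61.6 to 177), Dcx 28.0-fold (19.2 to 42.6), and Robo2, an axon guidance receptor, 55.6-fold (41.4 to 76.6). Pou5f1 was 7.37-fold lower (7.15 to 7.6), and pluripotency genes had a median of -1.01. Pdgfra, a growth factor receptor of mesenchymal cells, was 10.5-fold higher (8.99 to 12.2), with 2 of 23 fibroblast and matrix genes at least 4-fold higher. The size rule was met by 337 genes higher and 112 lower, which became 284 in all with a pseudocount of 2 CPM.

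Against the factors it was built from, the chimera library with no MOI label held lower levels of each program. That library also held 2.56-fold less Myod1 than MyoD (2.46 to 2.67), so construct and dose are not separated here. The chimera lacks the bHLH segment of Myod1, so this ratio may overstate the difference in dose. Of the 68 skeletal muscle structure genes 60 were at least 4-fold lower in the chimera than in MyoD, with a median of -3.65. Sln, a muscle calcium pump regulator, was 68.3-fold lower (40.5 to 125), and Klhl40, a sarcomere protein, 51.4-fold lower (36.6 to 74.5). Of the 81 neuronal structure genes 24 were at least 4-fold lower than in NeuroD2 and 0 higher, with a median of -1.64. Ina, a neuronal intermediate filament, was 28.1-fold lower (25.2 to 31.4) and Nkx6-1, a spinal progenitor factor, 30.6-fold lower (25.6 to 36.9). Over MyoD 220 genes were higher and 297 lower, and over NeuroD2 101 were higher and 257 lower. At MOI 100 the order depended on the gene. The chimera then held more Myog than MyoD (197 against 95.1 CPM) but less Myh3 (150 against 3060 CPM). It held more Neurod1 than NeuroD2 (150 against 111 CPM) but less Dcx (195 against 397 CPM).

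Sets drawn from the MyoD and NeuroD2 libraries were read in the chimera next. The 277 MyoD-activated genes, with a median log2 ratio of 4.24 in MyoD over GFP, had a median of 1.41 (1.17 to 1.60) in the chimera. The 478 NeuroD2-activated genes, with a median of 3.38 in NeuroD2, had a median of 1.52 (1.41 to 1.71) in the chimera. At least 4-fold higher were 26% of the first set (Clopper-Pearson interval 20.9% to 31.6%) and 29.1% of the second (25% to 33.4%). The 37 shared genes had a median of 2.34 (1.79 to 2.86). In unchanged libraries simulated against the same GFP library the set medians lay between 0.00 and 0.07. With sets drawn from MyoD against NeuroD2 alone, leaving GFP out of the definition, the chimera medians were 0.62 and 1.10. Of the 337 genes higher in the chimera, 124 were also higher in MyoD and 215 in NeuroD2, against 9.28 and 14.7 for independent lists. The lists share the GFP library, so independent lists are no measure of chance. No gene met the size rule in the simulated unchanged libraries, so the simulations give no overlap for chance. MyoD and NeuroD2 shared 64 genes, against 18.7 for independent lists. Part of the excess may come from the shared GFP library, which cannot be split.

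**Figure D2:**
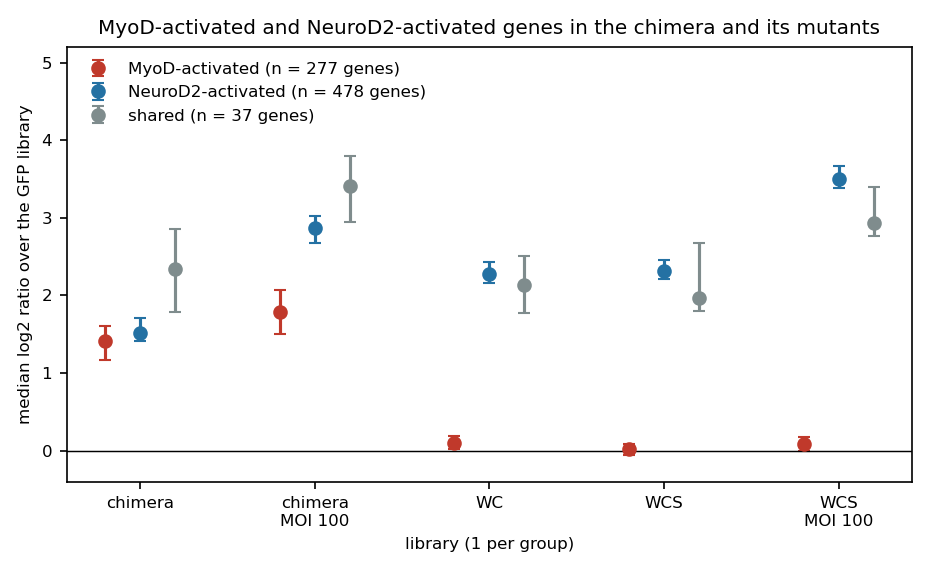
Median log2 ratio over the GFP library (vertical axis) of the MyoD-activated, NeuroD2-activated and shared gene sets in 5 libraries (horizontal axis), with order-statistic 95% intervals over member genes as bars. MyoD-activated genes lie at 1.41 and 1.78 in the chimera libraries and between 0.02 and 0.10 in the mutant libraries.

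The mutants WC and WCS were compared with the chimera to ask which genes differ between a mutant and the chimera. Muscle genes were lower in both. Of 68 skeletal muscle structure genes 27 were at least 4-fold lower in WC and 29 in WCS, 0 were higher in either, and the medians were -1.98 (-2.63 to -1.36) and -2.08 (-2.76 to -1.67). Myog was 907-fold lower in WC (251 to 7494) and at least 464-fold lower in WCS, where it had 0 counts (571-fold against the floor). Musk was 169-fold lower in WC (96.3 to 327) and 273-fold in WCS (132 to 681), and Atp2a1, the fast-muscle calcium pump, 78.8-fold (58.5 to 109) and 93.5-fold (67.1 to 135). Neuronal structure genes were higher, with medians of 0.82 in WC and 0.88 in WCS. Dcx was 8.76-fold (8.0 to 9.62) and 8.97-fold (8.19 to 9.85) higher, Ina 10.2-fold (9.14 to 11.4) and 12.6-fold (11.3 to 14.1), and Scrt1, a neuronal zinc-finger repressor, 12.5-fold (9.28 to 17.3) and 15.4-fold (11.4 to 21.2). Pdgfra was 9.39-fold (7.97 to 11.1) and 12.2-fold (10.1 to 14.8) lower. Rn7s6, a 7S RNA gene, was 23-fold (13.8 to 41.5) higher in WC and 25.5-fold (15.3 to 46.1) in WCS. It stood at 13.0 to 16.3 CPM in GFP, MyoD, WC and WCS and at 0.565 to 1.28 CPM in the other 4 libraries, so a split outside the muscle and neuron genes runs along this comparison. The same split runs along other comparisons. Among them are the chimera over GFP (28.8-fold lower, 17.4 to 51.8), NeuroD2 over GFP, MyoD over NeuroD2 and WCS at MOI 100 over WCS. Its source, which may lie in library preparation, was not tested. At MOI 100 Rn7s6 stood at 1.215 CPM in the chimera and 1.285 in WCS. Cell cycle genes had medians of -0.43 and -0.55, with 0 of 49 members 4-fold apart in either. The size rule was met by 73 genes higher and 88 lower in WC, and by 92 higher and 117 lower in WCS.

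Against GFP, the MyoD-activated set had medians of 0.10 (0.02 to 0.19) in WC and 0.02 (-0.05 to 0.09) in WCS, and 3.25% and 2.53% of its members were at least 4-fold higher. The NeuroD2-activated set had medians of 2.28 (2.16 to 2.43) and 2.31 (2.21 to 2.46), with 53.3% and 53.6% at least 4-fold higher. With sets drawn from MyoD against NeuroD2 alone, the MyoD-activated medians over GFP were -0.08 in WC and -0.17 in WCS. Over the chimera, a comparison sharing no library with the sets, MyoD-activated medians were -1.18 (-1.39 to -0.99) in WC and -1.36 (-1.54 to -1.06) in WCS. NeuroD2-activated medians were 0.77 (0.72 to 0.85) and 0.86 (0.77 to 0.94). For WCS over the chimera at MOI 100 the 2 medians were -1.63 and 0.72. Over GFP 399 genes were higher and 94 lower in WC, and 395 higher and 140 lower in WCS. Of the higher genes, 344 in WC and 341 in WCS were also higher in NeuroD2, against 17.5 and 17.3 for independent lists, and 48 and 47 were also higher in MyoD, against 11 and 10.9. These lists share the GFP library too, so the values for independent lists are no measure of chance here.

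WC and WCS were close to each other. By the size rule 2 genes were higher and 1 lower in WC. Ace, the angiotensin-converting enzyme, was 5.52-fold higher (4.08 to 7.61) and Adamts2, a procollagen protease, 5.24-fold (3.86 to 7.26). Across genes, which are not independent replicates, log2 CPM of the pair correlated at r = 0.997, and at 0.980 or less in every other pair of the 8 libraries. The pair still differed by more than counting noise: 26.7% of 14308 genes with 50 or more counts differed at a chi-square p under 0.05, against 63.8% to 87.3% in the 15 other pairs tested. Such a test compares 2 libraries, not the constructs.

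At MOI 100 the difference between WCS and the chimera had the same direction. The skeletal muscle structure median was -2.60 (-3.22 to -2.16), with 36 of 68 at least 4-fold lower, and the neuronal structure median was 0.75 (0.52 to 0.96). Actc1 was 222-fold lower in WCS (183 to 274), Atp2a1 354-fold (251 to 518) and Myog 1257-fold (538 to 3872). At MOI 100 Actc1 stood at 690 CPM in the chimera and 3.1 CPM in WCS, against 42.3 CPM in GFP and 5.69 CPM in NeuroD2. Part of its ratio is therefore a fall below the GFP level. Lhx9, a homeodomain factor of spinal and brain neurons, was 13.2-fold higher (11.5 to 15.3) and Barhl2, another neuronal homeodomain factor, 19.6-fold (14.1 to 28.0). In all 91 genes were higher and 190 lower.

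The 4 libraries of chimera and WCS were fitted together, since construct and MOI label cross in them. Most tested muscle genes fell in WCS, and more neuronal genes rose than fell. No camera list call held with an estimated correlation (adjusted p = 0.34 or more). That form of the test has 1 residual degree of freedom and can hardly reach small p-values, so it leaves the list calls unsettled. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Myog fell (adjusted p = 1.7e-05), with 0 counts in WCS and 5 in WCS at MOI 100 against 1545 and 5674 in the chimera libraries, as did Ttn (log2 fold change -6.93, adjusted p = 1.7e-05), Cdh15 (-6.51, adjusted p = 1.7e-05), Myh3, Musk, Klhl41, Mymk and Trim55, a sarcomere-associated ubiquitin ligase. Cdkn1a, the cell cycle inhibitor p21, fell by 3.41 on the log2 scale and Igf2, an imprinted growth factor, by 4.33. Lhx9 rose (3.76, adjusted p = 9.3e-05), as did Slc17a6 (2.77, adjusted p = 0.00011), Cntn2, an axonal adhesion protein, Nxph4, St18, Lhx2, Nefl, Gpm6b, Ina and Map6. Nhlh1 rose by 0.79, and Neurod1 (-0.14, adjusted p = 0.56), Pou5f1 (0.18, adjusted p = 0.72) and Myod1 (0.03, adjusted p = 0.96) did not pass. In all 939 genes rose and 882 fell of 16079 tested, and the DESeq2 Wald test called 1633, of which 1539 were the same genes. The p-values rest on 1 residual degree of freedom. Without the MOI term edgeR's test called 0 genes (1137 at an unadjusted p under 0.05). With 1 library left out and no MOI term, it called 103 genes without the chimera, 52 without the chimera at MOI 100, 0 without WCS (1317 at an unadjusted p under 0.05) and 0 without WCS at MOI 100 (1026), and without WCS at MOI 100 the log2 fold change of Nhlh1 was -0.05. Such fits partly mix construct with MOI label. The log2 fold change of Ttn ran from -7.85 without WCS at MOI 100 to -6.24 without the chimera at MOI 100. Lhx9 ran from 2.65 without WCS at MOI 100 to 4.89 without the chimera at MOI 100, and Slc17a6 from 1.64 to 4.0 without the same libraries. Cdh15 ran from -6.79 without WCS at MOI 100 to -6.26 without WCS, Igf2 from -4.74 to -3.94 without the same libraries, and Cdkn1a from -3.68 without the chimera to -3.06 without the chimera at MOI 100.

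By list, 54 of 63 tested skeletal muscle structure genes fell and 1 rose (camera adjusted p = 8.2e-38; adjusted p = 0.34 with an estimated correlation), or 56 and 2 adjusted over the list alone. Of 24 myogenic regulators 19 fell and 2 rose (3.3e-14; adjusted p = 0.34 with an estimated correlation), or 20 and 2 adjusted over the list alone. Of 81 neuronal structure genes 50 rose and 2 fell (2.2e-16; adjusted p = 0.34 with an estimated correlation), or 57 and 6 adjusted over the list alone, and of 58 neurogenic regulators 25 rose and 3 fell (2.2e-10; adjusted p = 0.44 with an estimated correlation), or 35 and 5 adjusted over the list alone. Of 49 cell cycle genes 31 fell and 0 rose (5.0e-14; adjusted p = 0.34 with an estimated correlation), or 41 and 0 adjusted over the list alone. Cardiac and smooth muscle (5 of 17 fell; camera adjusted p = 0.0017), fibroblast and matrix (5 of 22 fell; 0.022) and interferon and stress (3 of 27 fell, 1 rose; 0.024) also passed, at adjusted p = 0.44, 0.63 and 0.44 with an estimated correlation. Adjusted over the list alone, 6 of the cardiac and smooth muscle genes fell and 0 rose, 6 of the fibroblast and matrix genes fell and 1 rose, and 5 of the interferon and stress genes fell and 2 rose. None of these 8 camera calls held with an estimated correlation. That form of camera rests on the 1 residual degree of freedom, so small p-values were hardly within its reach. For myogenic regulators the estimated correlation of -0.043 lay below the preset 0.01, yet unadjusted camera p rose from 7.7e-15 to 0.073. It therefore cannot tell whether correlation between genes accounts for the calls, which stay unsettled. Camera adjusted p was 0.11 for pluripotency, where 0 of 32 rose and 1 fell (0 and 0 adjusted over the list alone), 0.31 for neural progenitor and Notch, where 10 of 37 rose and 8 fell (16 and 8 adjusted over the list alone), 0.44 for endoderm and mesoderm, where 3 of 21 rose and 4 fell (4 and 5 adjusted over the list alone), 0.76 for glia and neural crest, where 1 of 15 rose and 3 fell (3 and 3 adjusted over the list alone), and 0.066 for E-proteins with Id, Pbx and Meis, where 2 of 16 rose and 0 fell (2 and 0 adjusted over the list alone). With an estimated correlation these adjusted p were 0.49, 0.65, 0.63, 0.80 and 0.56. The glia and neural crest median was 0.01 while its mean was -0.43 and its camera direction was down. In fry, whose directional test asks whether a list's genes move on balance one way, the adjusted p was 0.0078 for myogenic regulators and 0.084 for skeletal muscle structure, neuronal structure, cell cycle, and interferon and stress. These fry values changed with the settings. Without the block they were, in that order, 0.092, 0.028, 0.56, 0.46 and 0.068. With DESeq2 size factors they were 0.033, 0.084, 0.11, 0.13 and 0.037.

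**Figure D3:**
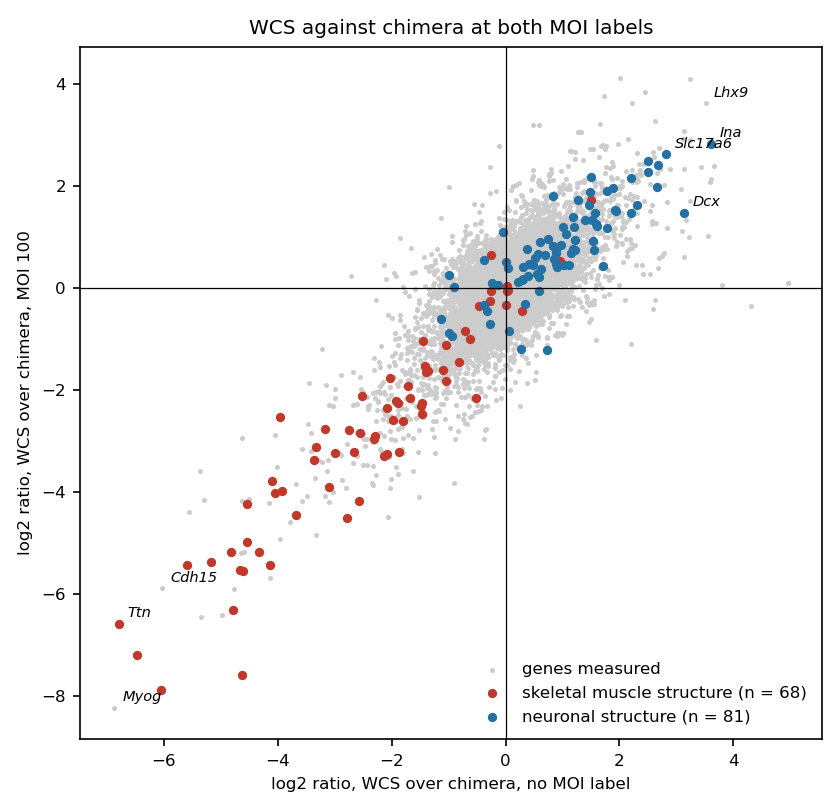
Log2 ratio of WCS over the chimera for each measured gene (points), without an MOI label (horizontal axis) and at MOI 100 (vertical axis), with skeletal muscle structure genes in red and neuronal structure genes in blue. The skeletal muscle structure medians are -2.08 and -2.60, and the neuronal structure medians 0.88 and 0.75.

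The last comparison set MOI 100 against the libraries with no MOI label. Neuronal structure genes were higher at MOI 100, with medians of 1.31 (1.16 to 1.47) in the chimera and 1.20 (1.07 to 1.34) in WCS. Skeletal muscle structure genes had medians of 0.43 (0.25 to 0.62) in the chimera and 0.00 (-0.10 to 0.09) in WCS. In the chimera Dcx was 10.2-fold higher (9.31 to 11.2) and Myog 3.38-fold (3.2 to 3.58), while Myh7, a slow myosin, was 3.8-fold lower (3.13 to 4.63). Nanog was 9.64-fold lower in the chimera (8.12 to 11.5) and 9.62-fold lower in WCS (8.24 to 11.3). Cell cycle genes had medians of -0.59 and -0.69. NeuroD2-activated genes had medians of 1.31 (1.26 to 1.38) in the chimera and 1.23 (1.17 to 1.31) in WCS, and MyoD-activated genes 0.40 (0.32 to 0.49) and 0.03 (-0.01 to 0.15). Ribosomal protein genes took 4.45% and 4.01% of counts at MOI 100, against 7.03% and 7.76% in the same constructs with no MOI label, 8.65% in GFP and 5.24% in NeuroD2. The size rule was met by 113 genes higher and 31 lower in the chimera, and by 111 higher and 72 lower in WCS. Over GFP it was met by 839 higher and 391 lower genes in the chimera at MOI 100, and by 850 higher and 467 lower in WCS at MOI 100.

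In the 4-library fit Ret, a neurotrophic receptor kinase, rose at MOI 100 (log2 fold change 2.74, adjusted p = 0.00062), as did Thsd7b (4.02), Rgs4 (2.71), the adhesion genes Cadm3 (2.18) and L1cam (2.34) and Scg2 (2.33), and Nanog (-3.27, adjusted p = 0.0007) and Pou5f1 (-2.68, adjusted p = 0.0013) fell, as did Myb, Plcg2, Sfrp1, Ripply1, Ezr, Pawr, Apoe, Nid2 and Foxh1. In edgeR's quasi-likelihood test 2153 genes rose and 1955 fell, and the DESeq2 Wald test called 3156, of which 3089 were the same genes. Without the construct term edgeR's test called 0 genes (3391 at an unadjusted p under 0.05). With 1 library left out and no construct term it called 0 genes each time, with 1796 at an unadjusted p under 0.05 without the chimera, 2771 without the chimera at MOI 100, 1998 without WCS and 1697 without WCS at MOI 100. In these fits Cadm3 ran from 1.21 without WCS at MOI 100 to 3.15 without WCS, and without the same libraries L1cam ran from 1.48 to 3.20, Rgs4 from 2.08 to 3.41, Ret from 2.25 to 3.21 and Thsd7b from 3.69 to 4.39. Scg2 ran from 2.12 without WCS to 2.54 without the chimera, Nanog from -3.37 without WCS at MOI 100 to -3.16 without the chimera at MOI 100, and Pou5f1 from -3.03 without the chimera to -2.31 without WCS. Whether the MOI effect differed between constructs was not tested, because no degree of freedom is left for it.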

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

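No test was chosen for the genes below after their values were seen, and with 1 library per group none of these differences was tested. Each gene here lay on opposite sides of no change in the same contrast in a pair of groups, with 1 library per group. Not every such gene is listed. Neurod1 stood at 120 CPM in WCS and 150 CPM in the chimera at MOI 100, and at 39.8 and 38.6 CPM with no MOI label. From no MOI label to MOI 100, Actc1 was 1.43-fold higher in the chimera and 6.13-fold lower in WCS, a difference of 3.14 on the log2 scale. Des, the muscle filament desmin, was 1.17-fold higher in the chimera and 3.09-fold lower in WCS (difference 1.86). In WCS at MOI 100 Actc1 and Des lay below GFP, at 3.1 against 42.3 CPM and 1.5 against 22.6 CPM. In NeuroD2 the 2 genes also lay below GFP, at 5.69 and 5.14 CPM. Dll1, a Notch ligand, was 1.13-fold higher in the chimera and 1.3-fold lower in WCS (difference 0.55). Rn7s6, a 7S RNA gene, was 2.15-fold higher in the chimera and 11.2-fold lower in WCS (difference 4.59), and it stood at 13.0 to 16.3 CPM in GFP, MyoD, WC and WCS and at 0.565 to 1.28 CPM in the other 4 libraries. From the chimera to WCS, Myod1 was 1.54-fold higher at MOI 100 and 1.5-fold lower with no MOI label (difference 1.21). Neurod4 was 1.15-fold lower at MOI 100 and 1.42-fold higher with no MOI label (difference -0.71), and Pou5f1 was 1.34-fold lower and 1.67-fold higher (difference -1.16).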

How the results depend on the processing

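No alternative here was chosen after the results were seen. With DESeq2 size factors all 48 counts of genes 4-fold apart, all 208 list medians and all 30 set medians stayed within their intervals or within 1.5 times, and 6 named ratios moved while 1302 did not. With total gene counts 172 named ratios moved while 1136 did not, as did 7 list medians. Depth limits ratios of genes near the floor of 3 counts. Causes were not tested, except that a stricter threshold or a larger pseudocount by construction leaves fewer genes and smaller ratios.

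At an 8-fold threshold the number of genes apart was 273 for MyoD over GFP, 411 for NeuroD2 over GFP, 587 for MyoD over NeuroD2, 180 for chimera over GFP, 228 for chimera over MyoD, 130 for chimera over NeuroD2, 56 for WC over chimera, 85 for WCS over chimera and 1 for WC over WCS. It was 102 for WCS over chimera at MOI 100, 11 for MOI 100 over no label in the chimera, 33 in WCS, 191 for WC over GFP, 211 for WCS over GFP, and 563 and 585 for the chimera and WCS at MOI 100 over GFP. With a pseudocount of 2 CPM it was 284 for chimera over GFP, 231 for chimera over NeuroD2, 93 for WC over chimera, 131 for WCS over chimera, 1 for WC over WCS, 177 for WCS over chimera at MOI 100, 77 and 94 for MOI 100 over no label in the chimera and WCS, and 313 and 353 for WC and WCS over GFP. With no minimum level WC over WCS gave 5.

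With a pseudocount of 2 CPM the skeletal muscle structure median was 4.76 for MyoD over GFP, 4.68 for MyoD over NeuroD2, 1.28 for chimera over GFP, -3.10 for chimera over MyoD, 1.44 for chimera over NeuroD2, -1.19 for WC over chimera, -1.36 for WCS over chimera, -1.66 for WCS over chimera at MOI 100 and 1.52 for the chimera at MOI 100 over GFP. The neuronal structure median was 1.36 for WC over GFP and the neurogenic regulator median 1.87 for NeuroD2 over GFP. The MyoD-activated median was 1.11 for the chimera and 1.42 for the chimera at MOI 100 over GFP, -0.96 for WC and -1.02 for WCS over chimera, and -1.32 at MOI 100. The NeuroD2-activated median over GFP was 1.24 for the chimera, 1.99 for WC, 1.99 for WCS, 2.49 for the chimera at MOI 100 and 3.22 for WCS at MOI 100.

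With sets at 8-fold the MyoD-activated median was 2.05 for the chimera and 2.47 for the chimera at MOI 100 over GFP, -1.76 for WC and -1.87 for WCS over chimera, and -2.27 for WCS over chimera at MOI 100. The NeuroD2-activated median over GFP was 2.01 for the chimera, 2.93 for WC, 2.92 for WCS, 3.50 for the chimera at MOI 100 and 4.45 for WCS at MOI 100. Over the chimera it was 0.94 for WC and 1.03 for WCS, 0.82 for WCS at MOI 100, and for MOI 100 over no label 1.55 in the chimera and 1.36 in WCS. The shared median over GFP was 3.0 for the chimera, 3.09 for WC, 3.11 for WCS, 4.41 for the chimera at MOI 100 and 4.51 for WCS at MOI 100, with 0.26 for WC over chimera, 0.62 for WCS over chimera at MOI 100 and 1.26 for MOI 100 over no label in the chimera. Genes higher in both libraries numbered 60 for chimera and MyoD, 88 for chimera and NeuroD2, 22 for MyoD and NeuroD2, 147 for WC and NeuroD2, 151 for WCS and NeuroD2, 17 for WC and MyoD and 17 for WCS and MyoD.

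With sets from MyoD against NeuroD2 only, the MyoD-activated median reversed to -0.08 for WC over GFP. It was 0.62 for the chimera, -0.17 for WCS, 0.78 for the chimera at MOI 100 and -0.36 for WCS at MOI 100 over GFP, -0.78 for WC and -0.87 for WCS over chimera, -1.09 at MOI 100, and 0.14 and -0.14 for MOI 100 over no label in the chimera and WCS. The NeuroD2-activated median over GFP was 1.10 for the chimera, 1.8 for WC, 1.78 for WCS, 2.23 for the chimera at MOI 100 and 2.79 for WCS at MOI 100, and 1.19 and 1.10 for MOI 100 over no label in the chimera and WCS. With no minimum level the MyoD-activated median was 1.16 for chimera over GFP, -0.99 for WC and -1.05 for WCS over chimera, and the NeuroD2-activated median over GFP was 2.17 for WCS, 2.66 for the chimera at MOI 100 and 3.37 for WCS at MOI 100. With total gene counts the NeuroD2-activated median was 0.78 for WCS over chimera at MOI 100 and 1.35 for MOI 100 over no label in WCS.

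In the 4-library fit, edgeR's test without the block called 0 genes for WCS against chimera (1137 at an unadjusted p under 0.05) and 0 for MOI 100 (3391), while DESeq2 with the block called 1633 and 3156. Without each library in turn it called 0 to 103 genes for WCS against chimera and 0 for MOI 100, where the lone library was assumed to vary like the others. The log2 fold change of Nhlh1 for WCS against chimera ran from -0.05 to 1.71, and for MOI 100 that of Myog ran from -7.48 to 14.52 and that of Mef2c from -0.83 to 2.29, with the lowest values without WCS at MOI 100 for Nhlh1 and without the chimera at MOI 100 for Myog and Mef2c. Myog had 0 counts in WCS, so its fitted values depend on the prior count and are no bounds. With an estimated correlation the camera adjusted p was 0.3441 for skeletal muscle structure, 0.3441 for myogenic regulators, 0.3441 for neuronal structure, 0.3441 for cell cycle, 0.4361 for neurogenic regulators, 0.4361 for cardiac and smooth muscle, 0.4361 for interferon and stress and 0.6272 for fibroblast and matrix. That form rests on 1 residual degree of freedom and can hardly give small p-values. Without the block the camera adjusted p of E-proteins with Id, Pbx and Meis was 0.03702, over a range up to 0.5612.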

Other observations

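Several genes stood at levels that differed widely between libraries, and those in this paragraph were chosen after their values were seen. Igf2 and H19, imprinted neighbours, stood at 1250 and 674 CPM in the chimera and 3540 and 892 CPM in MyoD. In WC they stood at 95 and 19.2 CPM, in WCS at 54.8 and 13.8, in the chimera at MOI 100 at 1689 and 533, in WCS at MOI 100 at 95.1 and 25, in GFP at 184 and 119 and in NeuroD2 at 237 and 176. Cdkn1a stood at 187 CPM in MyoD, 59.9 in the chimera and 92.4 in the chimera at MOI 100, against 5.98 to 13.4 CPM in the other 5 libraries. Pdgfra stood at 49.1 CPM in the chimera and 20 at MOI 100, against 1.69 to 7.69 CPM in the others. Lhx9 stood at 100 CPM in WCS at MOI 100, 30.6 in WCS, 18.6 in WC and 8.18 in NeuroD2. Nkx6-1 had the other order, at 144 CPM in NeuroD2 and 18.5 to 23.7 CPM in the mutant libraries. Slc17a6, of glutamate release, stood at 197 CPM in WCS at MOI 100, while Slc32a1, of GABA and glycine release, stayed at 1.17 CPM or less in the 8 libraries.

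The tests in the paragraphs below were chosen only after the results they bear on were seen, and the library pairs of the first and the gene filter of the next were revised after their first values were known; the first had used WCS at MOI 100 over the chimera alone, at -2.19, and the looser filter of the next had given the same reading. Muscle genes were higher than in GFP in both chimera libraries and not in its mutants. If less construct in the mutants were the cause, the muscle list would lie near 0 where a mutant library held 0.9 times or more of the Myod1 of a chimera library. Over 3 such pairs the highest list median was -1.98, for WC, which held slightly less Myod1 at 0.915 times. In the pairs at 7.41 and 1.54 times, where the mutant held more, the medians were -2.19 and -2.60, which argues against it. If RNA of the MyoD culture were the whole cause, each MyoD-activated gene would reach the same share of its MyoD increment. Over 65 genes the 75th percentile of that share was at least 3.13 times the 25th, which argues against it as the whole cause. Myog reached 61.2% while Myh3 reached 4.30% in the chimera. Unequal shares cannot exclude a smaller part from such RNA, which stays open. A difference between the chimera and its mutants in what the protein does was not tested and stays open, as do construct protein levels, harvest times and the handling of cultures and libraries. The split in Rn7s6 runs along the comparison with no MOI label and is absent at MOI 100, where the muscle list median was -2.60.

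WC and WCS were close to each other. If they were a single library under both labels, counts would differ by no more than counting noise, but 26.7% of genes with 50 or more counts differed at a chi-square p under 0.05, which argues against it. Whether the constructs act alike stays open with 1 library each.

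From no MOI label to MOI 100 of the chimera, neuronal genes were much higher and muscle genes little higher. If the culture only held more transduced cells of the same kind among GFP-like cells, every responding gene would gain by the same factor. The median factor was 3.21 (3.0 to 3.37) for 340 NeuroD2-activated genes and 1.59 (1.46 to 1.77) for 166 MyoD-activated genes, counting only members at least 2-fold above GFP in the chimera library, a ratio of 2.02, which argues against it as the whole cause. An effect of dose on which genes respond was not tested and stays open, as do differences in culture or harvest.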
